A study of Homo sapiens with 4 samples.

How the data were processed

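Total RNA of 2 parental and 2 ibrutinib-resistant TMD8 samples was hybridised to Affymetrix human transcriptome arrays with 1 channel each, and samples were grouped by the sample group that the labels give. The values are expression as deposited by the authors and were taken to be on a log2 scale, with 1 value per transcript cluster or probe set and array. Affymetrix Power Tools and Transcriptome Analysis Console are named, without version or role, per the submitters' processing notes. The summary method, background correction, normalization, log base and genome build were not given in the sources used here. Values ran from 1.96 to 19.93, and the maxima lie above 16, the log2 of a 16-bit scanner maximum, so the values are not plain log2 scanner intensities and every fold is on the deposited scale. Array medians were 3.95, 3.89, 3.95 and 4.01, and no further normalization was applied. The labelled spike controls bioB and bioC read 9.74 and 13.23 on resistant replicate 1, 11.05 and 14.56 on resistant replicate 2, and 10.51 to 10.73 and 14.04 to 14.17 on the parental arrays.

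The table held 70523 probe sets. The test used 67528 transcript clusters, and left out 1465 exon region or junction probe sets and 1530 other controls. Of the clusters 23781 had 1 gene symbol, 1543 several and 42204 no listed symbol in the platform annotation given, and 21497 of the first were matched to current RefSeq names (GRCh38.p14) by Entrez identifier. Each of 22401 genes was read from its single-symbol cluster with the highest mean. XIST, TSIX and Y-linked genes, 87 in all, were left out of the gene tables. Of 614 listed gene symbols 552 were measured, 4 of them through a synonym, and a list of mitochondrially encoded transcripts, 1 of 27 fixed, held 0 measured genes and was not tested. Some listed genes and the result of 1 further list are not reported here.

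Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), with Benjamini-Hochberg adjustment over all 67528 clusters and a threshold of 0.05. The fit had 2 residual and 2.6 prior degrees of freedom. An exact two-sided permutation test of 2 against 2 samples cannot go below 0.333, so that test cannot pass. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 26 lists, and again with an estimated correlation and with fry, which tests whether a set's genes move, on balance, one way. The antigenomic probe sets, 23 per array, gave the background. A group whose samples all lay at or under the brightest of them on their array was held to be under background, and the fold is then given as "at least", the brighter group's mean against the mean of the dimmer group's array limits. Where 1 of the dimmer group's 2 samples lay under background, "at least" sets that sample to its limit.

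Named genes followed a rule set before the data were examined. It took BCL2, BTK and PLCG2, the 10 genes with the largest change in each direction among those that passed with groups apart and a higher group mean above the median cluster mean of 3.95, and up to 4 members per list that passed. Other list members, BCL2 relatives and immunoglobulin genes given by value were chosen after their values were seen. The gene lists, the tests and most alternatives were also set before the data were examined. The alternatives were quantile normalization, median centring, an intensity trend, a robust prior, no moderation, a filter on dim clusters, other thresholds, the mean of a gene's clusters, coding genes alone and leaving out each array, where the lone sample left is assumed to vary like the other group. Of the rest, 1 use of identical clusters, the exon and junction probe sets and a background filter were added later.

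The fit was tested on simulated values for all 67528 clusters with the spread of these arrays, each cluster drawn independently of the others. With 200 clusters changed, 0, 42, 76 and 92% of those changed by a log2 of 1, 2, 4 and 6 were recovered and 0 unchanged clusters were called. With 8000 changed, 68.8, 90, 98.2 and 99.7% were recovered and 333 unchanged clusters were called. In a separate simulation, which raised the glycolysis list alone by a log2 of 1, that list was called and 0 others were. Simulated genes did not move together, so list calls among genes that do were not tested. Figures were drawn with matplotlib 3.10.9.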

Results

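Gene expression was measured in TMD8, an established human line of the activated B-cell type of diffuse large B-cell lymphoma. Ibrutinib is a covalent inhibitor of BTK, the kinase that carries B-cell receptor signals to PLCG2 and NF-kappaB. The 4 samples were 2 of parental cells and 2 of cells made resistant by long culture with ibrutinib at rising doses, each on its own Affymetrix human transcriptome array. The labels do not say whether ibrutinib was present when RNA was taken, nor whether the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Array medians lay between 3.89 and 4.01 on the deposited scale, which was taken to be log2. Between 15376 and 21166 of 67528 transcript clusters lay above the brightest antigenomic background probe set of their array. Across clusters, which are not independent replicates, Pearson's r was 0.993 between the parental arrays, 0.991 between the resistant arrays and 0.967 to 0.970 between groups. The number of arrays limits the precision of every value below.

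The study set out to compare the level of BCL2, the anti-apoptotic protein that venetoclax blocks, between parental and resistant cells. BCL2 (transcript cluster TC18000554.hg.1) rose from 12.23 ± 0.06 in parental cells to 14.31 ± 0.38 in resistant cells (mean ± SD, n = 2). The log2 difference was 2.08 (SE 0.21, limma adjusted p = 0.0159), or 4.22-fold on the deposited scale, and both resistant samples lay above both parental samples. The genome build of the array annotation was not given in the sources used here, so no coordinates are printed. Without parental replicate 1 the difference was 2.04 at an adjusted p of 0.0672, and without parental replicate 2 it was 2.12 at 0.0597. Without moderation of the variances the adjusted p was 0.316.

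Other apoptosis regulators moved both ways. BCL2A1, another anti-apoptotic family member and an NF-kappaB target, fell by 2.57 (SE 0.31, adjusted p = 0.0231), while MCL1 had a log2 difference of -0.87 (adjusted p = 0.0789), BCL2L1 0.44 (0.294) and XIAP 0.63 (0.127). Of 9 measured anti-apoptotic genes and inhibitors of apoptosis, 1 rose, 1 fell and 7 did not pass, and adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.552). Among pro-apoptotic members PMAIP1, which encodes NOXA, rose by 2.28 (SE 0.29, adjusted p = 0.0273). BID fell by 1.56 (adjusted p = 0.0333) and the pore-forming BAK1 fell by 1.41 (adjusted p = 0.0171, at least 2.29-fold). BCL2L11, which encodes BIM, had a difference of -1.22 that did not pass (adjusted p = 0.531). The pro-apoptotic list held 1 higher, 2 lower and 8 not passing of 11, and 2 and 2 adjusted over the list alone (camera adjusted p = 0.582).

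**Figure D1:**
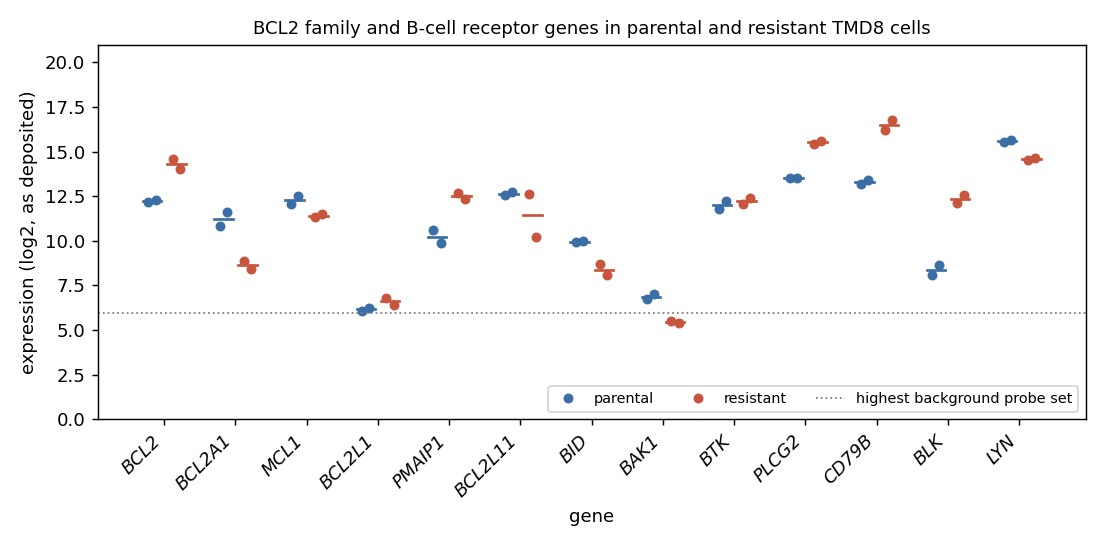
Deposited expression, taken as log2 (vertical axis), of BCL2 family and B-cell receptor genes (horizontal axis) in each of the 4 samples. Points are single samples, short lines are group means of n = 2, and the dotted line is the highest background probe set on any array, 5.97. BCL2 lies at 12.23 in parental and 14.31 in resistant cells, PLCG2 at 13.52 and 15.53, and the BTK samples of both groups overlap.

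The B-cell receptor pathway contained the drug's target and genes around it. BTK itself had a difference of 0.24 (SE 0.21, adjusted p = 0.668), with overlapping samples at 11.99 ± 0.31 in parental and 12.23 ± 0.27 in resistant cells. PLCG2, the phospholipase that BTK phosphorylates, rose by 2.01 (SE 0.12, adjusted p = 0.00659). BLK, a SRC-family kinase, rose by 3.97 (SE 0.27, adjusted p = 0.00827), and CD79B, a signalling chain of the receptor, by 3.23 (SE 0.22, adjusted p = 0.00854). INPP5D, the phosphatase SHIP1, rose by 1.87 (adjusted p = 0.0329), as did PRKCB by 1.52 (0.0475) and IGHM by 1.68 (0.0352), whereas the kinase LYN fell by 1.02 (0.0199). Of 31 measured genes 6 rose, 1 fell and 24 did not pass, against 8 and 5 adjusted over the list alone. As a list these genes did not stand apart from the rest (camera adjusted p = 0.794). PLCG2, BLK and CD79B each lie in a stretch of neighbouring expressed genes that was higher. The stretches run from SF3B3 to FBXO31 (51 genes, median log2 difference 0.58), ERICH1 to PNOC (51, 0.78) and MTMR4 to SLC39A11 (58, 0.61). For PLCG2, BLK and CD79B, a change of the pathway and a shift of the stretch were not told apart.

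Targets of NF-kappaB changed in both directions. The chemokine gene CXCL10 fell by 3.94, at least 3.51-fold since resistant samples lay under background, and BCL3, a nuclear NF-kappaB cofactor, fell by 1.72 (SE 0.12, adjusted p = 0.00862, at least 2.52-fold). IRF4 (-1.63) and BATF (-1.37), transcription factors of activated B cells, and BCL2A1 were the other genes that fell. CCL4, a chemokine induced by receptor signalling, rose by 2.92 (SE 0.45, adjusted p = 0.0408), at least 4.10-fold, and REL by 1.33 (0.0131). NFKBIE had a difference of 3.93 that did not pass (adjusted p = 0.0514). The list of 32 held 2 higher, 5 lower and 25 not passing, and 5 and 11 adjusted over the list alone (camera adjusted p = 0.091).

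Genes used to tell lymphoma subtypes apart split within the activated B-cell list. PIM1, a serine/threonine kinase, rose from 13.14 to 17.10 (SE of the difference 0.30, adjusted p = 0.0101), and ETV6 rose by 2.21 (0.0182) and FOXP1 by 1.66 (0.00774). PIM1 lies in a stretch of 94 neighbouring expressed genes, from SNRPC to FAM135A, that was higher (median 0.97). A change of PIM1 alone and a shift of that stretch were not told apart. The phosphatase PTPN1 fell by 2.95 (SE 0.24, adjusted p = 0.0113) and STAT3, which acts downstream of interleukin receptors, by 2.59 (SE 0.21, adjusted p = 0.0112). In this list of 19, 6 rose, 5 fell and 8 did not pass, with 10 and 7 adjusted over the list alone (camera adjusted p = 0.582). Of 18 germinal-centre genes 0 rose and 3 fell, SERPINA9 (at least 1.69-fold) and LMO2 (at least 1.055-fold), which lay under background in resistant samples, and GCSAM, which lay under background in both groups. BCL6 had a difference of 1.73 that did not pass (adjusted p = 0.0887). Adjusted over the list alone, 3 germinal-centre genes were higher and 6 lower (camera adjusted p = 0.183).

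B-lineage identity genes were lower in resistant cells as a list, with 0 of 20 measured genes higher and 7 lower (camera adjusted p = 0.0206, and adjusted p = 0.997 with an estimated correlation). TCL1A, an AKT co-activator expressed in immature and naive B cells, fell from 13.19 ± 0.14 to 5.96 ± 0.19, a difference of -7.23 (SE 0.15, adjusted p = 0.00304, at least 143-fold). FCRL5, an Fc receptor-like protein of B cells, fell by 5.78 (SE 0.21, adjusted p = 0.00401, at least 34.5-fold). The transcription factors SPIB (-1.74), IKZF1 (-1.72), CIITA (-1.56) and TCF3 (-1.29) and the invariant chain CD74 (-1.94) also fell. PAX5 had a difference of -0.14 (adjusted p = 0.619) and MS4A1, which encodes CD20, -0.44 (0.281). The counts were 5 higher and 9 lower adjusted over the list alone. The call on this list was lost with each array centred on its median (adjusted p = 0.103), with a filter on dim clusters (0.101), without parental replicate 2 (0.102) and without resistant replicate 1 (0.0563).

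Among plasma-cell and secretory genes PRDM1, the repressor that drives plasma-cell differentiation, fell from 11.66 ± 0.01 to 5.51 ± 0.17, a difference of -6.15 (SE 0.13, adjusted p = 0.00304, at least 58.2-fold). SUB1 fell by 3.03 and the elongation factor ELL2 by 2.66, and IRF4 fell as above. CD38, a surface ectoenzyme, rose by 3.79 (SE 0.22, adjusted p = 0.00645). JCHAIN had a difference of -3.93 that did not pass (adjusted p = 0.0641). Of 20 genes 1 rose, 4 fell and 15 did not pass, with 3 and 7 adjusted over the list alone (camera adjusted p = 0.352).

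Interferon-stimulated genes were higher in resistant cells, with 8 of 28 measured genes higher and 0 lower (camera adjusted p = 4.62e-08, and adjusted p = 0.997 with an estimated correlation). IFI44L rose from 4.07 ± 0.00 to 11.59 ± 0.52, a difference of 7.52 (SE 0.26, adjusted p = 0.00401). Both parental samples of IFI44L lay under background, so the rise was at least 86.0-fold. IFI6, a mitochondrial interferon-induced protein, rose by 5.85 (SE 0.54, adjusted p = 0.0136), IFI44 by 4.23 (SE 0.11, at least 7.10-fold) and the antiviral GTPase MX1 by 3.61 (SE 0.21). XAF1 (2.55, at least 5.24-fold), EPSTI1 (2.09), IFIT3 (1.96, at least 3.58-fold) and OASL (1.42, at least 1.51-fold) rose as well. ISG15 (0.44) and IRF7 (0.29) did not pass and lay under background in both groups. Adjusted over the list alone, 17 rose and 1 fell, and the list kept its call without each of the 4 arrays in turn.

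**Figure D2:**
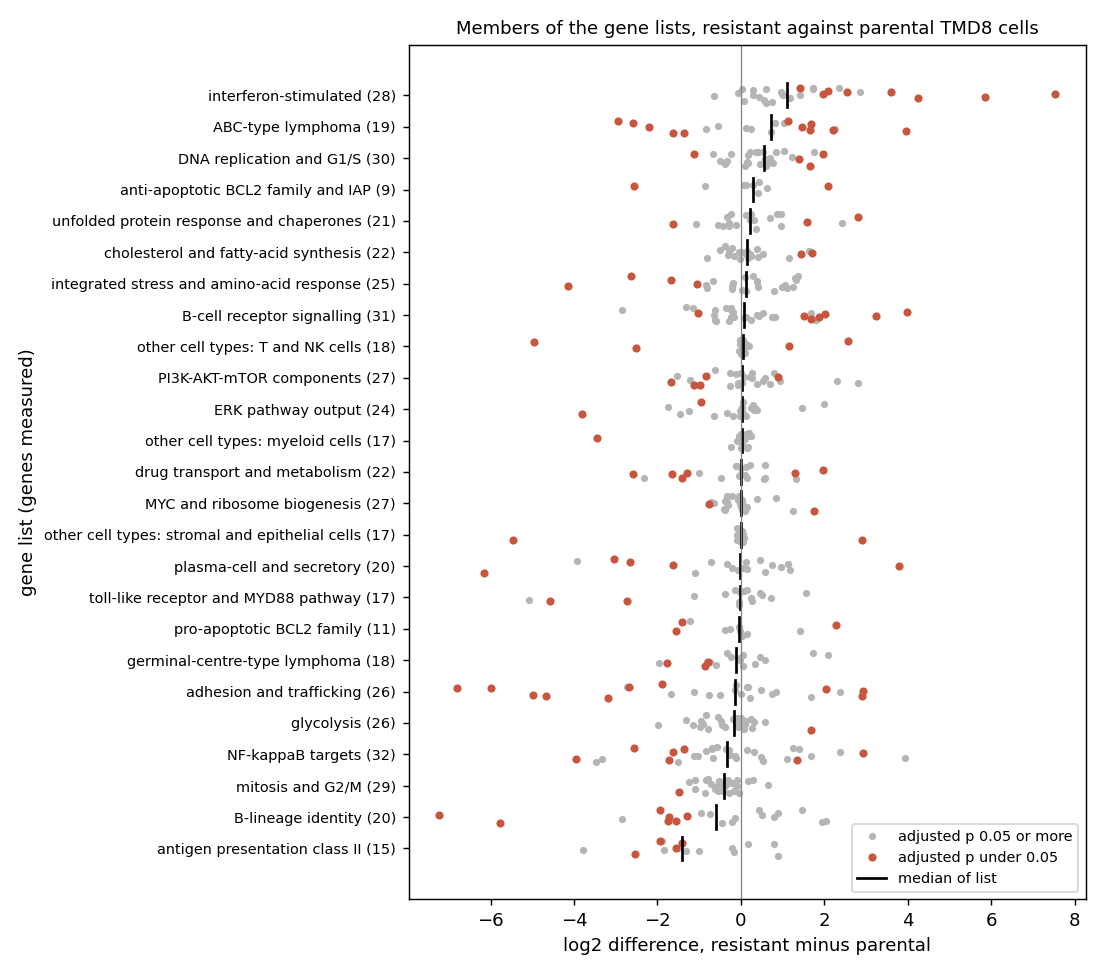
Log2 difference between resistant and parental cells (horizontal axis) for each member of the gene lists described (vertical axis, genes measured in parentheses). Points are genes, red where the adjusted p was under 0.05 over all clusters, and bars are list medians. The interferon-stimulated list has the highest median, 1.10, and the class II list the lowest, -1.42.

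Class II antigen presentation was lower in resistant cells, with 0 of 15 genes higher and 4 lower (camera adjusted p = 0.000527, and adjusted p = 0.997 with an estimated correlation). HLA-DRA, the alpha chain of HLA-DR, fell from 17.35 ± 0.43 to 14.81 ± 0.43, a difference of -2.54 (SE 0.30, adjusted p = 0.0227). CD74, the class II chaperone, fell by 1.94, the transactivator CIITA by 1.56 and HLA-DPB1 by 1.42, at least 2.14-fold. HLA-DQA1 (-3.78, adjusted p = 0.0699) and HLA-DRB1 (-1.88, 0.0805) did not pass, and the peptide editors HLA-DMA and HLA-DMB had differences of 0.88 and 0.18. The HLA class II genes are neighbours, in a stretch of 48 expressed genes from GPANK1 to PHF1 that was lower (median -0.55, 6 above 0). CD74 and CIITA lie outside it. For the HLA genes, a change of this pathway and a shift of that stretch were not told apart. The counts were 0 higher and 9 lower adjusted over the list alone, and the list kept its call without each array in turn.

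Adhesion and trafficking genes included some of the widest falls. GPR183, an oxysterol receptor that positions B cells in follicles, fell from 12.84 ± 0.37 to 6.04 ± 0.95, a difference of -6.79 (SE 0.49, adjusted p = 0.00901, at least 90.3-fold). The chemokine receptor CXCR4 fell by 5.99 (SE 0.23, adjusted p = 0.00434) and ITGAL, the alpha chain of LFA-1, by 4.99 (SE 0.32, adjusted p = 0.00785, at least 28.4-fold). ITGA4, the alpha chain of VLA-4, fell by 4.68 to a level under background, at least 11.3-fold. CD58 (-3.18, at least 7.06-fold), SIGLEC10 (-2.68) and ITGAX (-1.90, at least 1.96-fold) also fell, while PECAM1 (2.90, at least 4.12-fold), CCL4 and ICAM2 (2.05, at least 3.64-fold) rose. Of 26 genes 3 rose, 7 fell and 16 did not pass, with 7 and 12 adjusted over the list alone (camera adjusted p = 0.157).

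The cell-cycle lists moved apart. DNA replication genes were higher as a list, with 3 of 30 higher and 1 lower (camera adjusted p = 0.00915, and adjusted p = 0.997 with an estimated correlation). SLBP, which binds histone messenger RNA, rose by 1.97 (SE 0.16, adjusted p = 0.0108), GINS2 of the replicative helicase by 1.65 (0.017) and the histone chaperone CHAF1A by 1.39 (0.0404), while thymidylate synthase TYMS fell by 1.12 (0.0184). Mitosis genes were lower as a list although 1 of 29, the spindle protein NUSAP1, fell on its own (-1.48, SE 0.17, adjusted p = 0.0218) and 28 did not pass. Camera gave the mitosis list an adjusted p of 0.00107, and an adjusted p of 0.997 with an estimated correlation. Adjusted over the list alone, 11 replication genes rose and 2 fell, and 0 mitosis genes rose and 3 fell. The replication call was lost without parental replicate 1 (adjusted p = 0.095) and resistant replicate 1 (0.254), and the mitosis call without parental replicate 2 (0.121) and resistant replicate 2 (0.166).

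In the ERK, toll-like receptor and PI3K pathways single genes changed while the lists did not pass. DUSP5, a nuclear ERK phosphatase, fell by 3.81 (SE 0.20, adjusted p = 0.00566) and IER2 fell by 0.97 (at least 1.67-fold), the 2 genes of 24 ERK output genes that passed. EGR1 (1.99) and MYC (-0.65) did not pass, and 12 of the 24 lay under background in both groups. TLR7, an endosomal RNA receptor, fell by 4.58 to a level under background, at least 10.4-fold, and IRAK3 by 2.74, at least 2.84-fold. MYD88 had a difference of 0.23 (adjusted p = 0.771), and 15 of 17 genes of that pathway did not pass. Of 27 PI3K, AKT and mTOR components PDPK1 rose by 0.90, and DDIT4 (-1.68), PIK3R5 (-1.13, at least 1.87-fold), MTOR (-0.98) and AKT1 (-0.84) fell. For ERK output 1 gene rose and 4 fell adjusted over the list alone, for the toll-like receptor pathway 1 and 3, and for PI3K components 6 and 7. Camera adjusted p was 0.582 for ERK output, 0.787 for the toll-like receptor pathway and 0.993 for PI3K components.

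Metabolic and stress genes moved singly. SLC7A11, the cystine transporter, fell by 4.15 (SE 0.45, adjusted p = 0.0184, at least 13.7-fold) and SLC7A5, a leucine transporter, by 2.63 (SE 0.31, adjusted p = 0.0229). With ATF3 (-1.06, at least 1.82-fold) and DDIT4, 4 of 25 stress and amino-acid response genes fell and 0 rose. EDEM1 (2.80) and DNAJC3 (1.57) rose and SEL1L (-1.63) fell among 21 chaperone and unfolded protein genes. ENO2 (1.69) was the 1 glycolytic gene of 26 to pass, LSS (1.43) and SC5D (1.70) rose among 22 lipid synthesis genes, and LYAR (1.76) rose and MYBBP1A (-0.76) fell among 27 MYC and ribosome genes. Among 22 drug transport and metabolism genes GSTP1 (-2.58, SE 0.14, adjusted p = 0.00593), GSTM1 (-1.66, at least 3.07-fold), HMOX1 (-1.40, at least 2.12-fold) and ABCB4, under background in resistant samples, fell and GCLC (1.96) and ABCC1 (1.30) rose. The efflux pumps ABCB1 and ABCG2 lay under background in both groups.

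Adjusted over the list alone, the counts higher and lower were 1 and 5 for stress response, 4 and 2 for chaperones, 1 and 0 for glycolysis, 3 and 1 for lipid synthesis, 2 and 1 for MYC and ribosome genes and 5 and 7 for drug metabolism. Camera passed none of these 6 lists, with adjusted p from 0.352 for glycolysis to 0.794 for the stress response. List median, mean and camera direction differed in sign for ERK output, the stress response, MYC and ribosome genes, drug metabolism and the 3 lists of other cell types.

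Markers of other cell types lay mostly under background in both groups, 14 of 18 for T and NK cells, 15 of 17 for myeloid cells and 14 of 17 for stromal and epithelial cells. The exceptions that passed included GZMB, granzyme B, which fell by 4.97 (SE 0.44, adjusted p = 0.0131, at least 23.1-fold), CD5 (-2.53, at least 4.05-fold), CD68 (-3.46, SE 0.21, adjusted p = 0.00682, at least 10.5-fold) and E-cadherin CDH1 (-5.45, SE 0.23, adjusted p = 0.00457, at least 30.7-fold). PRF1 rose by 2.56, at least 3.57-fold, CD247 by 1.14, at least 1.24-fold, and PECAM1 by 2.90. Adjusted over each list alone the counts were as over all clusters, 2 and 2, 0 and 1, and 1 and 1. The 3 lists had camera adjusted p of 0.794, 0.993 and 0.794.

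Genes were ranked by fitted log2 difference, which is no bound where a sample lay under background, so the order of such genes is not established. In that order the widest rises after IFI44L were in LILRA4 (6.62, SE 0.61), a receptor of plasmacytoid dendritic cells, the arginine transporter SLC7A2 (5.91, at least 39.4-fold), IFI6, the cytokine receptor IL17RB (5.79, SE 0.72) and N-cadherin CDH2 (5.38, SE 0.54). FMOD (5.35, at least 20.6-fold), INPP5F (5.35), the sphingosine phosphate phosphatase SGPP1 (5.32) and the small nucleolar RNA SNORD116-15 (5.24, SE 0.31) completed the 10. AHR, the ligand-activated aryl hydrocarbon receptor, had the widest fitted fall, from 14.20 ± 0.27 to 6.63 ± 0.79 (-7.57, SE 0.40, adjusted p = 0.00574). PARM1 (-7.55, at least 168-fold), IGKV2D-28 (-7.24, at least 96.5-fold), TCL1A, EMP3 (-6.98), IGKV2-28 (-6.97), MIR3689C (-6.96), MIR3689B (-6.81), GPR183 and IQGAP2 (-6.43, at least 66.6-fold) followed. In all, 1819 of 22401 genes passed, 898 higher and 921 lower, of which 708 and 727 differed by a log2 of at least 1. Of 67528 transcript clusters 1738 were higher and 1721 lower, and of 17068 protein-coding genes 735 were higher and 849 lower.

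The gene count moved with each array left out, to 636 without parental replicate 1, 830 without parental replicate 2, 494 without resistant replicate 1 and 505 without resistant replicate 2, of which 563, 725, 417 and 424 were among the 1819. Of 91 genes that the rule for named genes took and that passed, 36 passed in all 4 of those fits, PLCG2, BLK, CD79B, PRDM1, TCL1A, CXCR4, IFI44L, AHR and STAT3 among them, and 15 passed in 0, HLA-DPB1, NUSAP1, TYMS and MTOR among them.

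Immunoglobulin segments were looked at further after 2 kappa segments appeared among the widest falls, so these genes were chosen after their values were seen. The heavy-chain constant gene IGHM rose from 17.40 to 19.08 (1.68, SE 0.24, adjusted p = 0.0352), while IGHA1 fell to a level under background, at least 14.2-fold, and IGHG4 by 3.11. IGHV3-48 fell by 5.92 and IGKV2-28 from 15.44 to 8.47. In resistant cells IGHV4-61 (2.30), IGHV4-59 (1.73), IGKV3D-11 (2.27), IGKV3D-15 (2.61) and IGLV2-18 (4.49, SE 0.56, adjusted p = 0.0252) were higher. IGKV3D-20 had means of 8.27 and 11.27, a difference that did not pass (adjusted p = 0.0801). Of 101 V clusters 6 rose and 13 fell, and probes of related segments can read each other's transcripts.

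**Figure D3:**
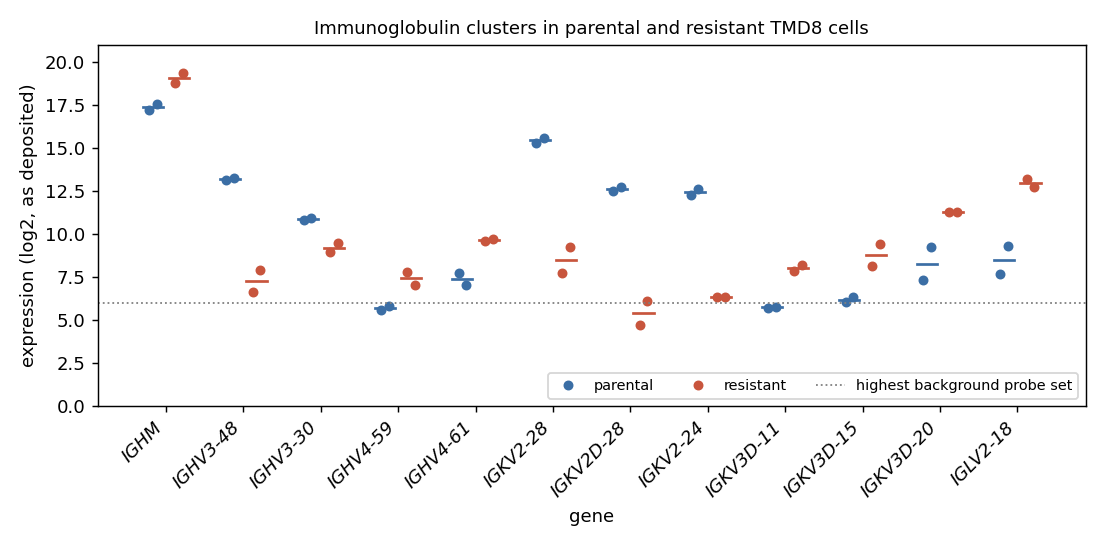
Deposited expression, taken as log2 (vertical axis), of 12 immunoglobulin clusters (horizontal axis) in each of the 4 samples. Points are single samples, short lines are group means of n = 2, and the dotted line is the highest background probe set on any array, 5.97. IGKV2-28 lies at 15.44 in parental and 8.47 in resistant cells, and IGHM at 17.40 and 19.08.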

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

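The comparisons with background-filtered genes, identical clusters used once, and exon and junction probe sets were chosen after seeing the data. All 1819 genes kept their sign without each array in turn, which is no independent check, since they were selected on these same arrays. No named gene changed sign under any alternative. Without each array in turn the genes higher ranged from 242 to 418 and lower from 237 to 412, the clusters higher from 477 to 764 and lower from 445 to 770, the lists called from 3 to 5, and the BCL2 difference from 1.80 to 2.35; fewer samples were fitted there. At an adjusted p under 0.01, 115 genes were higher and 164 lower, and 229 clusters were higher and 296 lower. Without moderation, which leaves 2 degrees of freedom, limma called 0 genes and 0 clusters in either direction, with 8698 clusters at an unadjusted p under 0.05, a smallest adjusted p of 0.192 and BCL2 at 2.08 (adjusted p = 0.316, against 0.0142 to 0.0672 under the other alternatives). Gene and cluster counts under the other alternatives stayed within 1.5 times. With an estimated correlation camera called 0 lists (0 at an unadjusted p under 0.05), and fry called 0 (8 unadjusted, smallest adjusted p 0.0696). A robust prior called 8 lists, adding adhesion, NF-kappaB targets and plasma-cell genes; the cause was not tested.

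Of the genes taken by the rule for named genes other than BCL2, 90 passed, of which 86 kept the call with quantile normalization, 82 with median centring, 83 with an intensity trend, 87 with a robust prior, 89 with the dim filter and 0 without moderation. Glycolysis was called, as lower, without resistant replicate 1, and NF-kappaB targets, as lower, without resistant replicate 2. Some lists not called with all 4 arrays turned direction. The PI3K list turned down with an intensity trend, a robust prior and fry (median 0.037 in each) and among genes above background (-0.065), the T and NK list with a robust prior and fry (0.045) and above background (-2.53), the stress list turned up with median centring (0.077), drug metabolism above background (0.18) and glycolysis with fry (-0.16). Without each array in turn the medians ranged from -0.10 to 0.29 for the B-cell receptor, -0.044 to 0.073 for ERK output, 0.0044 to 0.18 for PI3K and -0.36 to -0.030 for glycolysis. They ranged from -0.30 to 0.40 for stress, -0.083 to 0.053 for drug metabolism, 0.0044 to 0.067 for T and NK, -0.024 to 0.10 for myeloid and -0.049 to 0.044 for stromal genes. The cause was not tested. Signal over background limits dim genes, since 11863 of 22401 genes lay under background on all 4 arrays. No paired analysis was possible because the labels give no replicate numbers.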

Other observations

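Small nucleolar RNAs of the SNORD116 and SNORD115 families, which lie in an imprinted cluster and are processed from long host transcripts, were higher in resistant cells. These families were chosen after their values were seen. Of 19 SNORD116 genes 17 rose and 0 fell, with a median log2 difference of 3.08, and of 31 SNORD115 genes 24 rose and 0 fell. In parental samples 6 SNORD116 and 19 SNORD115 genes lay under background, and with groups under background set to their arrays' limits the medians were 2.90 and 1.72. Other C/D box small nucleolar RNAs had a median of 0.05 and 5 higher and 3 lower of 123, a median that turned to -0.0045 with median centring. Members of each family are close copies whose probes can read each other. All 5 MIR3689 microRNA genes, also close copies, fell, with a median of -5.63.

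The genes of this paragraph were also chosen after their values were seen. Of 6 FCRL receptors 3 fell, and of 10 SIGLEC receptors 2 fell and 6 lay under background in both groups. FCRL2 fell by 5.09 (SE 0.20, adjusted p = 0.00434, at least 19.8-fold), FCRL3 by 5.66 (SE 0.33, adjusted p = 0.00643, at least 35.2-fold) and SIGLEC6 by 6.19 (SE 0.18, adjusted p = 0.00341). FCRL1 had a difference of 0.10 that did not pass (adjusted p = 0.621). Of 533 ZNF zinc-finger genes 105 rose and 26 fell, 15 of them under background in both groups, against 898 and 921 of all 22401 genes. With median centring 67 ZNF genes rose and 23 fell. Whether the ZNF changes follow gene position was not tested. TIPARP, a target gene of AHR, fell by 1.22 (adjusted p = 0.0142), while CYP1A1 and CYP1B1 lay under background in both groups.

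The tests of lower transcription and of admixture, that of unscaled array differences and the random orders of scaled ones were chosen only after the results were seen. Of 101 V clusters 13 fell and 6 rose in resistant cells. Lower immunoglobulin transcription as a whole is argued against by IGHM, which rose by 1.68, although IGHA1 and IGHG4 fell. As a heavy-chain gene, IGHM does not test kappa transcription, and of 39 kappa V clusters 9 fell and 3 rose. A minor admixture of other B cells in the resistant cultures is argued against by the 39 V clusters above background in both parental samples. Of these, 11 fell by over 1 log2 unit, 7 of them by over 3, and 8 rose by over 1, each by over 2 SE. Dilution by a minor share lowers signal by under 1 unit if the deposited scale is log2 and follows cell share, which was not tested, and close copies can read each other. The test does not cover other B cells in the parental cultures that were absent from the resistant ones. An origin of the resistant samples in other cells may also give this pattern, and of 10 measured genes with common germline null alleles 3 lay under background in parental samples and 0 of the 3 were gained, too few to exclude it. In that set HLA-DRB4 (-3.90) and GSTM1 (-1.66) fell and CHI3L2 rose (1.35), while UGT2B17 (-2.32) did not pass, values that do not decide it. Loss of the rearranged genes alone does not account for the 8 V clusters that rose. An origin in other cells, a subline with other rearrangements and such a loss with a further change cannot be told apart here. Genotypes were not analysed here.

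BCL2 could be higher through more copies of its region. The median log2 difference of the 20 nearest expressed genes, without BCL2 itself, was -0.18, with a bootstrap interval from -0.52 to 0.77. Against the medians of all windows of 21 neighbouring expressed genes, which include their centre gene, this median lay at percentile 26.2. It depends on where the window lies, since 8 windows of 21 genes that contain BCL2, within 28 genes from POLI to CYB5A (median 0.37), and the window from MEX3C to BCL2 (0.59) had medians above 0.5. Among the 20 nearest genes 2 rose, PMAIP1 and TMX3, and 2 fell, ZNF532 and TNFRSF11A. The interval is too wide to exclude a gain, which cannot be told apart from regulation of BCL2 alone, and DNA copy number was not analysed here.

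Neighbouring genes shifted together between groups. Of 7564 windows of 21 neighbouring expressed genes, 1379 had a median beyond 0.5 in size, against at most 103 in 1000 random gene orders, which argues against chance order. The regions included 122 genes from ALG8 to DCPS (median 0.96) and 109 from SUSD6 to TMEM121 (-0.96). TCL1A lies in the latter, and AHR lies in 106 genes from USP42 to GUSB (-0.77). PRDM1 fell although it lies in 88 genes from CEP162 to RPS12 that were higher (0.68). Differences between the 2 parental arrays, scaled to the spread of the group difference, gave 1085 such windows, against at most 321 in 1000 random orders, and those between the resistant arrays 364, against at most 235, so array noise also follows gene position and a positional array bias may contribute, although unscaled they gave 39 and 10. A bias shared by both arrays of a group and copy-number changes both stay open. Leaving out single arrays cannot remove a bias that both arrays of a group share.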
